A study of Mus musculus with 6 samples.

How the data were processed

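RNA was measured in the first 2 cm of duodenum below the stomach, taken from 6-week-old mice of mixed background. Per the labels' protocols, tissue was kept in RNAlater, RNA was purified with RNeasy Midi kits, and libraries were made with the TruSeq RNA kit and sequenced on a HiSeq instrument. Of the 6 libraries, 3 came from controls and 3 from mutants in which the intestine carried Nkx2.2 only as the SD allele. The genotypes of the controls differ from one another, and mutants 1 and 3, which share a genotype, differ in sex, so the libraries were taken as 6 mice (n = 3 per group). No 2 libraries held identical values.

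The authors' upstream steps are known only in outline. CASAVA 1.8.2, TopHat, Cufflinks, DESeq and the mouse build mm9 are named in the submitters' processing notes, with no settings. Per the file headers, each library has a table of FPKM per gene and one per isoform, as fragments per kilobase and per M mapped reads, where M stands for mega, with RefSeq identifiers. The isoform tables deposited by the authors also give the read coverage of each isoform, an unscaled signal, and its length in bases. A table of the authors' own comparison, deposited for the whole series, gives the DESeq group means of normalized counts, their fold change as a ratio, its log2 value, a p-value and an adjusted p-value. It gives no value per library, so it was used only to describe. FPKM values depend on how reads were shared among isoforms and among near-identical genes, and the authors' settings for this are not given in the sources used here. The FPKM of a transcript shorter than the sequenced fragments is sensitive to the length correction.

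The gene tables held 23699 rows, of which 344 had no successful estimate in at least 1 library. First, 464 rows with a repeated symbol were dropped in favour of the row with the highest mean, which left 23235 symbols. Then 207 symbols whose row had no successful estimate were left out, among them Cd36, Pla2g2a and Per1, and 23028 were used. For 10 of the 207 a dropped row did have one. The isoform tables held 30028 rows, of which 518 were left out for lack of a successful estimate.

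Depth was read from the isoform coverage. Coverage times the length less 210.3 bases, over the read length of 101 bases, gave whole reads within 0.05 for 83.2% to 84.6% of values, and for 89.6% to 91.1% of values under 50 reads. The scaling of FPKM to coverage put the controls at 21.4, 19.6 and 21.3 M reads and the mutants at 19.1, 21.9 and 22.9 M. Read numbers are quoted as the depth behind a value. They are estimates, and reads without molecular identifiers are not independent molecules, so an interval on them covers counting error only.

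The main test was limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance, on log2(FPKM + 0.1) for genes with a mean of at least 0.2 FPKM over the 6 libraries. It was two-sided, mutant minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes. Isoforms were tested in the same way. Count tests were planned for deposited counts or recoverable reads. They were not run, since no table held counts per library and the reads recovered here are estimates from coverage, of which only 83.2% to 84.6% came out whole. As a replacement chosen after seeing the data, limma-voom was run on the recovered reads. The main limma fit on log2(FPKM + 0.1) was tested on simulated data over 14544 genes with 3 libraries against 3. Of 100 genes changed 2-fold it recovered 70, and of 100 changed 4-fold it recovered 95. It called 3 unchanged genes in that simulation, and 0 when no gene was changed. The changed genes were drawn only from better-covered genes, and noise was drawn separately for each gene. With no gene changed, 4.83% of simulated genes had an unadjusted p under 0.05, against 2.84% of genes in the real data. The simulation thus differs from the real libraries, where recovery may be lower.

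Before the data were examined, 34 gene lists were fixed, covering endocrine genes, other epithelial cells, immune and stromal cells, neighbouring organs, gut position and metabolism. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The test was repeated with an estimated correlation and with fry, and members were also counted when adjusted over the list alone. The rule for named genes was also fixed then. It takes Nkx2-2, any tested member of the lists of enteroendocrine hormones, serotonin and enterochromaffin genes and enteroendocrine transcription factors, and up to 4 members with the smallest p of each other list. It also takes the 10 higher and 10 lower genes with the largest change among those past the threshold, if the groups do not overlap and the higher mean is at least 1 FPKM; no gene passed. Sex-linked genes are named only in the sex check. Genes outside the rule are said to have been chosen after their values were seen.

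Sex is not in the labels and was read from Xist and 4 Y-linked genes. Each group held 1 male and 2 females. Alternatives covered the pseudocount, the filter on low values, quantile and TMM-type scaling, the variance trend, array weights, a term for the replicate number, a sex term, each library left out in turn, the list tests and the window around Nkx2-2. Scaling moved the median log2 change of all genes little: it was 0.0042 as deposited, -0.014 with quantile normalization and 0.00082 with TMM-type scaling. Coordinates are on mm9 and count from 1, so starts are 1 above those in the tables. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.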

Results

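The data set holds RNA-seq profiles of the first 2 cm of duodenum from 6 mice aged 6 weeks, 3 controls and 3 intestine-specific Nkx2.2 mutants. Nkx2.2, encoded by Nkx2-2, is a homeodomain transcription factor of endocrine cells in the gut and pancreas. The mutants carried a floxed Nkx2-2 allele, removed in intestinal epithelium by Villin-Cre, opposite an SD allele, which changes the NK2-specific domain of the protein. The controls carried no Cre: one had a floxed allele and a Rosa26 Tomato reporter, one the reporter alone, and one was wild type. Mutants 1 and 3 carried the reporter too, and mutant 2 did not. The depth was 19.6 to 21.4 M reads in controls and 19.1 to 22.9 M in mutants. Values are mean FPKM ± SD of 3 mice per group unless stated otherwise. The comparison asks how duodenal gene expression, above all that of the endocrine cells, differs when the epithelium has only the SD form of Nkx2.2. Every mutant also differs from every control by Villin-Cre, by loss of the floxed copy in epithelium, and by an SD allele in other cells. These cannot be told apart from the SD form in epithelium, for any difference reported below.

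The transcript of the targeted gene was present in every library. Nkx2-2 lies on chromosome 2 from 147003282 to 147012138, on mm9. Its level was 1.07, 0.647 and 0.716 FPKM in controls 1 to 3 and 0.564, 0.772 and 0.910 FPKM in mutants 1 to 3. The log2 change was -0.10 (SE 0.26), with a mean of 30 reads in controls and 25.7 in mutants. An exact two-sided permutation test gave p = 0.8, where 3 mice against 3 cannot give less than 0.1. The SD of each group exceeded the difference, and the sign turned without control 1 (0.10) or mutant 1 (0.07). The gene total showed no clear fall with the floxed allele removed, though with this SE a moderate fall cannot be excluded. The total level of the transcript does not show which form of the protein it encodes, so it checks the genotype labels only in part. The reference transcript NM_010919, of 2049 bases, had 0.729 ± 0.188 FPKM in controls and 0.479 ± 0.083 FPKM in mutants, with a log2 change of -0.50 (SE 0.29; limma adjusted p = 1.0). The other transcript, NM_001077632, of 1354 bases, lay below the filter and was not tested. It went the other way, with 0.150, 0.099 and 0 FPKM in controls and 0.135, 0.338 and 0.334 FPKM in mutants, on 4, 2 and 0 reads and 3, 8 and 9 reads.

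Hormone genes moved in both directions. Ghrl, which encodes ghrelin, rose from 95.4 ± 27.3 to 237 ± 25.3 FPKM, a fitted 2.55-fold difference on the log2(FPKM + 0.1) scale (log2 change 1.35, SE 0.21). Sst, which encodes somatostatin, rose from 86.0 ± 15.8 to 136 ± 15.1 FPKM (log2 change 0.67, SE 0.15). Nts, which encodes neurotensin, fell from 1.83 ± 0.355 to 0.308 ± 0.228 FPKM (log2 change -2.44, SE 0.49), with a mean of 36.7 reads in controls and 6.67 in mutants. Without mutant 1, which had 1 read, its log2 change was -1.84. Pyy, which encodes peptide YY, fell from 10.8 ± 5.17 to 4.28 ± 1.88 FPKM (log2 change -1.30, SE 0.39). Gast, which encodes gastrin, stood near the limit of detection, with 1 read in the 3 controls and 22 reads in the 3 mutants. The read ratio was 21.4, with an exact 95% interval of 3.46 to 884 for counting error only. Its mutant values were 3.00, 1.30 and 0.178 FPKM, and the lowest of them lay below the highest control value of 0.191 FPKM.

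Of 12 hormone genes tested, 3 were higher and 2 lower at an adjusted p under 0.05 when adjusted over the list alone, and 7 did not pass. The limma values adjusted over the list alone were 0.0037 for Ghrl, 0.0093 for Nts, 0.010 for Sst and 0.031 for both Pyy and Gast. Over all genes tested, 0 of the 12 passed in the limma fit. In the authors' deposited DESeq comparison, Ghrl and Nts did pass over all genes (adjusted p = 1.64e-07 and 0.00058). Ghrl, Nts and Sst passed over the list alone in each of the 17 other settings run, which include leaving out each mouse. Pyy and Gast did not: over the list alone their values reached 0.098 without mutant 1, and Pyy was at 0.055, 0.085 and 0.083 without control 2, control 3 and mutant 2. For Gast the corresponding values were 0.063, 0.088 and 0.083. With no filter both stood at 0.0505, with limma-voom Pyy stood at 0.060 and Gast at 0.084, and Gast stood at 0.064 with a pseudocount of 1 and at 0.060 with array weights. Over the list alone 3 hormone genes passed with no filter and with limma-voom, and 9 with a replicate term. As a list the hormones showed no common direction, with a median log2 change of 0.02 (camera adjusted p = 0.988).

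Among hormone genes that did not pass, Gcg, which encodes proglucagon, was at 6.76 ± 1.8 FPKM in controls and 4.11 ± 1.35 FPKM in mutants. Ucn3, which encodes urocortin 3, was at 1.20 ± 0.201 and 0.825 ± 0.105 FPKM, and Tac1, which encodes substance P, at 11.6 ± 2.24 and 8.23 ± 2.84 FPKM. Sct, which encodes secretin, was at 120 ± 20.2 and 144 ± 13.8 FPKM, and Iapp, which encodes amylin, at 1.73 ± 0.844 and 2.99 ± 1.56 FPKM. For Gip and Cck the log2 changes were 0.11 (SE 0.17) and -0.07 (SE 0.13), at mean levels of 168 and 69.6 FPKM in controls. The sign turned for Gip without control 2 or mutant 1 (both -0.04), and for Cck without control 3 (0.01) or mutant 3 (0.0021).

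Genes of serotonin-producing enterochromaffin cells were lower in the mutants as a list. Of 11 tested, 9 had lower means, and the median log2 change was -0.48 (camera adjusted p = 3.83e-05; adjusted p = 0.837 with an estimated correlation). Trpa1, an irritant-sensing ion channel of these cells, fell from 1.48 ± 0.363 to 0.683 ± 0.069 FPKM (log2 change -0.995, SE 0.21). It was the 1 member that passed when adjusted over the list alone (adjusted p = 0.023), and 0 passed over all genes. Without control 3 or mutant 1 it stood at 0.076 and 0.074, and no member passed in either case. Under other settings the number of members that passed was 2 with no filter, with a filter of 1 FPKM and without the trend, 3 with a pseudocount of 1 and with limma-voom, 4 with quantile normalization and 5 with a replicate term. Tph1, the rate-limiting enzyme of serotonin synthesis in the gut, was at 9.95 ± 1.85 FPKM in controls and 6.87 ± 0.645 FPKM in mutants, and all 3 mutants lay below all 3 controls. Lmx1a, a transcription factor of enterochromaffin cells, was at 0.598 ± 0.067 and 0.328 ± 0.055 FPKM, also without overlap. Both stood at 0.056 when adjusted over the list alone. Reg4 was at 134 ± 40.2 and 87.9 ± 24.4 FPKM, and the vesicular monoamine transporter gene Slc18a1 at 4.45 ± 1.04 and 3.41 ± 0.339 FPKM. Ddc, which many epithelial cells also express, and Gch1 had higher means, with log2 changes of 0.51 (SE 0.41) and 0.23 (SE 0.22). For Fev and Slc38a11 the log2 changes were -0.18 (SE 0.30) and -0.20 (SE 0.40), and the signs turned without control 1 (0.02) or mutant 2 (0.04) for Fev and without control 3 for Slc38a11 (0.13).

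**Figure D1:**
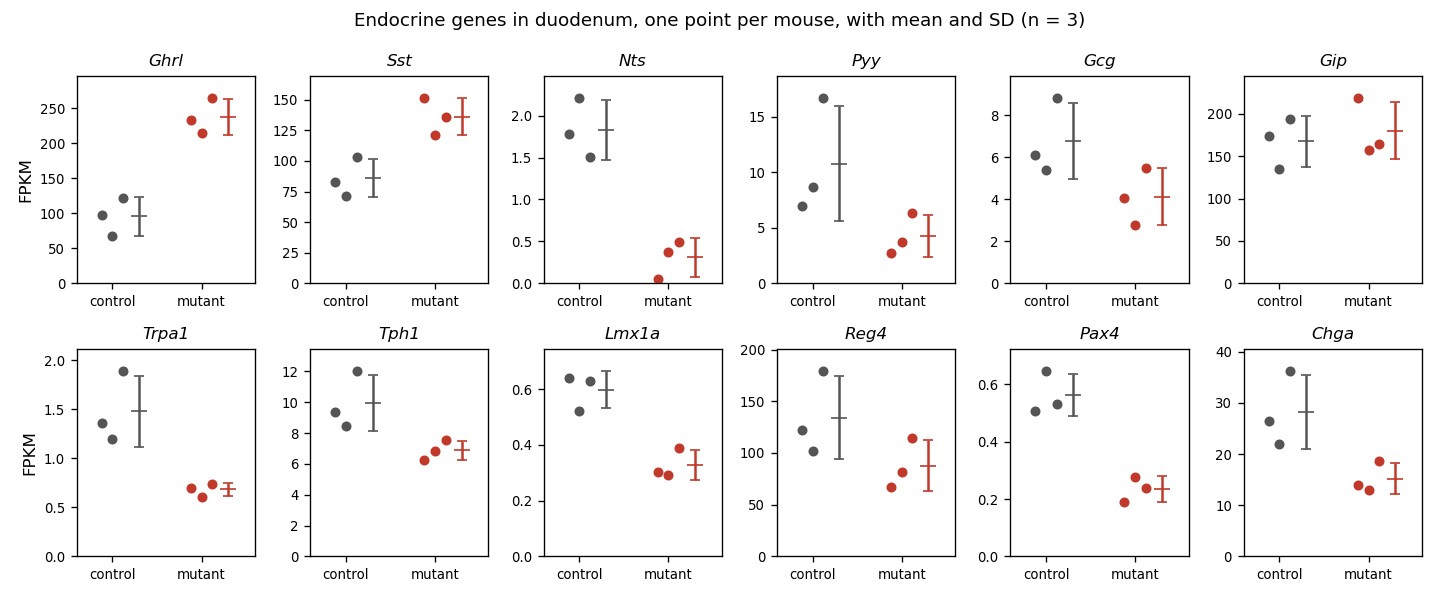
FPKM of 12 endocrine genes in control and mutant duodenum, on linear axes from 0. Each point is 1 mouse, and the bar beside the points is the mean with its SD of 3 mice; Ghrl and Sst lie higher in the mutants, at 237 and 136 FPKM, and Nts, Pyy and Trpa1 lower, at 0.308, 4.28 and 0.683 FPKM.

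The transcription factors of the endocrine lineage showed no common direction. Of 16 tested, 7 had higher and 9 lower means, 0 passed when adjusted over the list alone or over all genes, and the camera adjusted p was 0.498. Over the list alone 1 passed with no filter and 2 without the trend. Pax4, a factor of early endocrine cells, was at 0.562 ± 0.074 FPKM in controls and 0.235 ± 0.044 FPKM in mutants, without overlap, on a mean of 13 and 5.67 reads (limma adjusted p = 0.068 over the list alone). Pax6 was at 0.271 ± 0.028 and 0.448 ± 0.152 FPKM, and Isl1 at 0.765 ± 0.213 and 1.06 ± 0.106 FPKM. Neurog3, which starts the endocrine program, had 2.26 ± 0.458 and 2.45 ± 0.599 FPKM, and its log2 change of 0.10 (SE 0.23) turned to -0.06 without control 2 and -0.03 without mutant 2. Neurod1 had a log2 change of -0.08 (SE 0.23), which turned to 0.0082, 0.03 and 0.03 without control 1, mutant 1 and mutant 3. Insm1 had one of 0.16 (SE 0.25), which turned to -0.06 without control 2. Rfx6 had a log2 change of -0.36 (SE 0.35).

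Genes of the secretory granule shared by endocrine cells did not move as a list (20 tested, 0 passed over the list alone; camera adjusted p = 0.527). Their member with the smallest p was Chga, which encodes chromogranin A. It was at 28.2 ± 7.25 FPKM in controls and 15.2 ± 2.96 FPKM in mutants without overlap (log2 change -0.88, SE 0.21), and stood at 0.075 when adjusted over the list alone.

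Across the transcriptome, limma called 0 of 14642 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 416 genes, 290 higher and 126 lower, which is 2.84% of those tested, where chance gives 5%. Other 3-against-3 splits of the same libraries gave 214 to 1396 such genes, most of them more than 416. The values of the groups did not overlap for 1108 genes (7.57%), where chance gives 10%. The smallest adjusted p was 0.191, for Afp, the alpha-fetoprotein gene, which was at 13.1 ± 3.41 FPKM in controls and 2.46 ± 0.591 FPKM in mutants. Limma-voom on the recovered reads also called 0 genes, with 376 at an unadjusted p under 0.05. The authors' deposited table, from DESeq, lists 5 genes at an adjusted p under 0.05 and 208 at an unadjusted p under 0.05. In the authors' deposited table Mt1 was 3.09-fold higher, Ghrl 2.43-fold higher and Rps18 3.48-fold higher, while Afp was 5.34-fold and Nts 6.13-fold lower. Their DESeq adjusted p were 2.57e-08 for Mt1, 1.64e-07 for Ghrl, 0.0046 for Rps18, 3.20e-05 for Afp and 0.00058 for Nts. Mt1, a metal-binding metallothionein gene, had 457 ± 163 and 1372 ± 168 FPKM. All 5 had the same direction in the limma fit. Afp, Mt1 and Rps18 were chosen after their values were seen. For Rps18, a ribosomal protein gene with many copies in the genome, the fitted ratio on the log2(FPKM + 0.1) scale was 1.41 (53.3 ± 9.40 and 74.4 ± 2.80 FPKM), so its size is uncertain. The comparison took 13967 genes present in both, with a finite log2 change and past a minimum mean count. Of these 93.7% had the same sign, and Spearman's rho of the log2 changes was 0.946. Both rest on the same libraries, and genes are not independent replicates.

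Of the 34 gene lists, 7 passed the camera threshold, 3 higher and 4 lower in mutants, while with an estimated correlation 0 passed. The estimated correlation within these 7 lists ran from 0.11 for serotonin genes to 0.84 for cholesterol synthesis, all above the preset 0.01. Every other 3-against-3 split of the libraries also passed at least 7 lists, and up to 22. The number of lists passed therefore does not set the real groups apart. Limma-voom called 11 lists, and 6 to 12 passed with one mouse left out. Fry called 0 lists in one direction and 4 in its mixed test, which asks for change in either direction. These 4 were the hormones (adjusted p = 0.0082), the serotonin genes (0.040), the endocrine transcription factors (0.0045) and the mast cell and eosinophil markers (0.026).

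Markers of mast cells and eosinophils had a median log2 change of 0.47 over 8 tested genes (camera adjusted p = 0.0063; adjusted p = 0.902 with an estimated correlation). Mcpt4, a mast cell protease gene, rose from 0.311 ± 0.076 to 0.894 ± 0.137 FPKM on a mean of 5 and 15 reads, and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0075). Cpa3 was at 0.666 ± 0.253 and 1.38 ± 0.605 FPKM, and Mcpt1 at 9.68 ± 1.33 and 19.4 ± 9.46 FPKM. In mutants 1 to 3 Cpa3 was at 0.716, 1.54 and 1.90 FPKM and Mcpt1 at 8.45, 24.4 and 25.2 FPKM. Mutant 1, the male, thus lay within the control range for both, and only mutants 2 and 3 were higher. Without mutant 2 or mutant 3 the list stood at 0.094 and 0.067, and without mutant 1 at 8.56e-07. Markers of B cells and plasma cells had a median of 0.26 over 9 genes (camera adjusted p = 0.0026; adjusted p = 0.844 with an estimated correlation). Among them Cd79a, a part of the B cell receptor, was at 13.8 ± 0.539 and 16.5 ± 1.37 FPKM, and Tnfrsf17 at 8.81 ± 1.72 and 11.9 ± 2.26 FPKM. This list kept its call without each mouse in turn, at adjusted p of 0.0029 to 0.016. T cell, macrophage and MHC class II lists did not pass (camera adjusted p = 0.527, 0.273 and 0.245).

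Paneth cell markers all had log2 changes above 0, with a median of 0.33 over 10 genes. The camera adjusted p was 0.0063, and 0.916 with the estimated correlation of 0.63. The markers thus moved together and are not 10 independent observations. Ang4, an antimicrobial ribonuclease gene, was at 1176 ± 281 and 1497 ± 187 FPKM. Defa17 was at 9698 ± 3109 and 12360 ± 1820 FPKM, and Defa21 at 0.169 ± 0.068 and 0.492 ± 0.298 FPKM, on a mean of 0.722 and 2.11 reads. These defensin genes share sequence with close copies and are uncertain, and 0 members passed over the list alone. Without control 1, control 2 or mutant 1 the list stood at 0.158, 0.367 and 0.086, and with array weights at 0.0595. Goblet cell markers (camera adjusted p = 0.076), tuft cell markers (0.527), stem cell markers (0.527) and proliferation genes (0.988) did not pass. In these lists Tff3 was at 3539 ± 309 and 4385 ± 440 FPKM, Ltc4s at 8.78 ± 2.12 and 12.6 ± 2.79 FPKM, Olfm4 at 271 ± 74.8 and 223 ± 21.4 FPKM, and Mcm6 at 28.0 ± 4.02 and 30.0 ± 2.25 FPKM. The stem cell marker Lgr5 had a log2 change of -0.22 (SE 0.26), which turned to 0.0016 without mutant 1. The proliferation genes had a mean of 0.0060 and a median of -0.0080, and camera placed them lower.

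Cholesterol synthesis genes all had lower means in mutants, with a median of -0.22 over 16 genes. The camera adjusted p was 0.0026, and 0.916 with the estimated correlation of 0.84. The members thus moved together and are not 16 independent observations. Sc5d, a sterol desaturase gene, was at 53.2 ± 8.5 and 44.1 ± 5.07 FPKM. Without control 1, control 2 or mutant 1 the list stood at 0.120, 0.504 and 0.227. Interferon response genes had a median of -0.11 over 18 genes (camera adjusted p = 0.0074; adjusted p = 0.902 with an estimated correlation). Zbp1 was at 55.2 ± 4.27 and 45.4 ± 6.22 FPKM, and Ifit1 at 20.5 ± 3.45 and 15.5 ± 4.38 FPKM. Without control 2, control 3 or mutant 1 the list stood at 0.168, 0.128 and 0.807. Neither list had a member that passed over the list alone.

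The absorptive epithelium gave no list call. Camera adjusted p was 0.245 for brush border enzymes and transporters, 0.527 for dietary lipid absorption, 0.076 for iron and calcium handling and 0.075 for PPAR-alpha fatty acid oxidation. Sucrase-isomaltase, Sis, was at 285 ± 24.4 and 247 ± 67.2 FPKM, Dpp4 at 77.3 ± 11.4 and 65.9 ± 5.45 FPKM, and Apob at 175 ± 6.96 and 157 ± 18.4 FPKM. The calcium channel gene Trpv6 was at 82.3 ± 20.5 and 111 ± 15.6 FPKM. Cyp4a10, a fatty acid hydroxylase gene, was at 3.74 ± 1.81 and 9.08 ± 2.99 FPKM.

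Tissue next to the sampled segment was followed with its own markers. Pancreatic acinar markers had a median of -1.40 over 14 genes (camera adjusted p = 0.030; adjusted p = 0.916 with an estimated correlation), at low and uneven levels. Cpb1, a pancreatic carboxypeptidase gene, was at 1.53, 0.199 and 1.46 FPKM in controls and 0.082, 0.852 and 0.068 FPKM in mutants, and Ctrl at 2.21 ± 0.709 and 1.41 ± 0.262 FPKM. Without control 1, control 3, mutant 1 or mutant 3 the list stood at 0.506, 0.397, 0.526 and 0.201, and it lost its call under 6 of the other settings, at 0.053 to 0.153. Stomach and Brunner gland markers did not pass as a list (median 0.80 over 8 genes; camera adjusted p = 0.223). When adjusted over the list alone, 2 members passed. Tff1 rose from 0.709 ± 0.595 to 2.18 ± 0.215 FPKM, on a mean of 4 and 12.5 reads, though the authors' deposited table lists it at 0 in both groups. Ctse, the gene for cathepsin E, rose from 27.9 ± 4.18 to 47.6 ± 14.9 FPKM. Both stood close to the threshold, at 0.047 and 0.0498, and each passed in only part of the settings. Over the list alone Tff1 was at 0.058, 0.149, 0.099, 0.055 and 0.093 without control 2, control 3 and mutants 1, 2 and 3, and at 0.083, 0.051 and 0.057 with no filter, a replicate term and no variance trend. Ctse was at 0.080, 0.055, 0.149, 0.099 and 0.093 without controls 1, 2 and 3 and mutants 1 and 3, and at 0.051 to 0.083 under 7 other settings. Gif, the intrinsic factor gene of gastric cells, was at 0.742, 0.039 and 0.427 FPKM in controls, on 21, 1 and 12 reads, and is listed at 0 in each mutant. It stood at 0.051 when adjusted over the list alone.

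The remaining lists did not pass. Camera adjusted p was 0.381 for antimicrobial lectins and inflammation, 0.970 for fibroblasts, 0.576 for smooth muscle, 0.220 for endothelium and 0.521 for enteric neurons and glia. It was 0.351 for pancreatic islets, 0.880 for proximal and 0.527 for distal gut position, 0.576 for circadian clock genes, 0.075 for immediate early genes, 0.700 for blood cell genes and 0.880 for sex genes. The neuropeptide gene Vip was at 26.9 ± 2.31 and 22.4 ± 2.13 FPKM, Egr1 at 2.65 ± 0.126 and 3.46 ± 0.568 FPKM, and the neutrophil gene S100a9 at 0.521 ± 0.026 and 0.949 ± 0.197 FPKM on 3 and 5.67 reads.

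**Figure D2:**
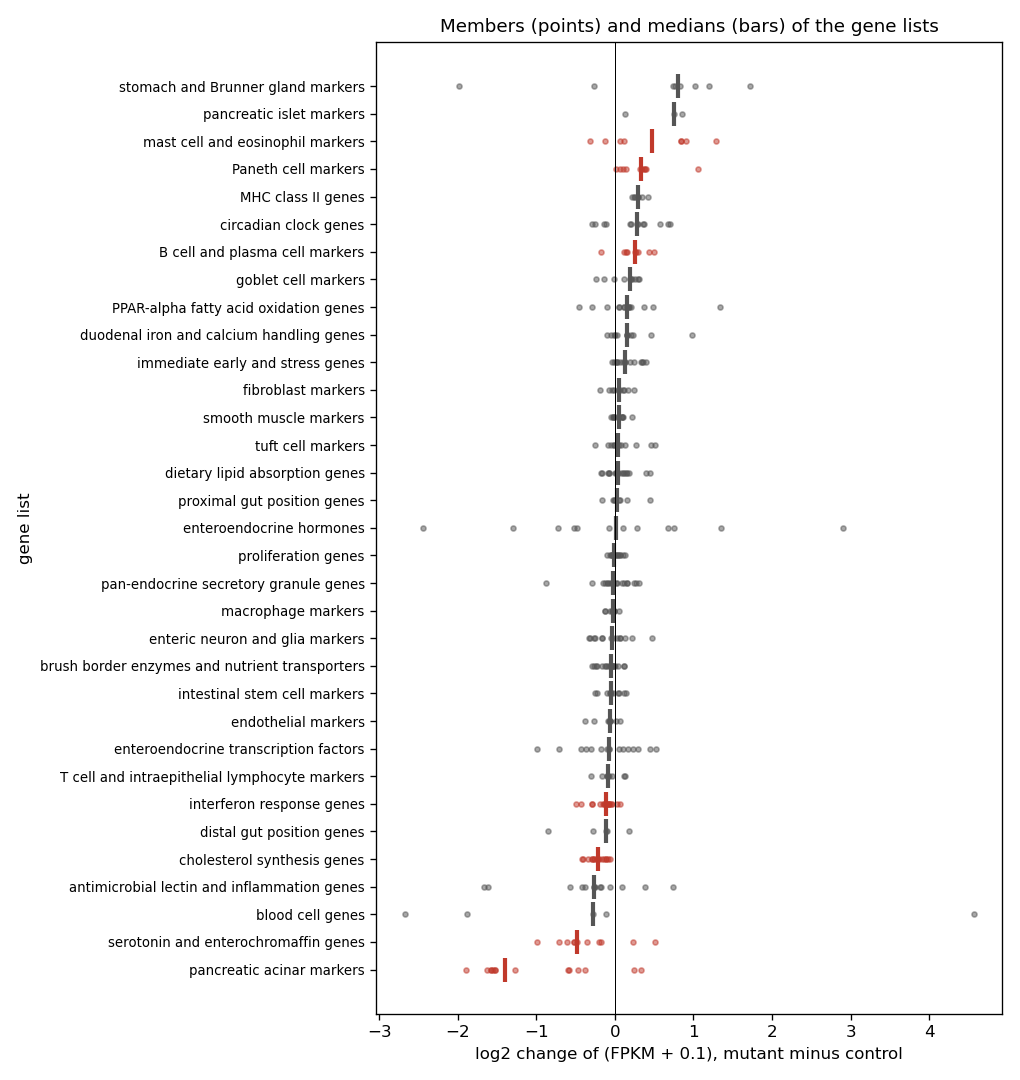
Log2 change of FPKM + 0.1, mutant minus control, for the members (points) and the median (bars) of the gene lists other than the sex genes, with the lists that passed the camera threshold in red. The hormone list spreads to both sides of 0, from Nts at -2.44 to Gast at 2.90, while the serotonin list has its median at -0.48.

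At the level of single transcripts, limma called 5 of 17922 isoforms, 4 higher and 1 lower, with 633 at an unadjusted p under 0.05. They were named after their values were seen. Capg NM_007599 (8.88 ± 2.56 FPKM in mutants), Ccdc116 NM_001164606 (3.17 ± 0.505), Eif5 NM_178041 (5.17 ± 2.38) and Repin1 NM_175099 (1.73 ± 0.396) were estimated below 0.02 FPKM in each control. Cpne1 NM_170588 was at 1.92 ± 0.420 FPKM in controls and below 0.001 FPKM in each mutant. Their limma adjusted p ran from 0.0056 to 0.049. The genes as a whole had log2 changes of -0.07, 0.22, -0.05, 0.29 and -0.03 in that order. The count of isoforms was 0 without control 1 and 9 without control 3. It was 3 with a pseudocount of 1, 1 with a filter of 1 FPKM and 0 with a replicate term.

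Genes near the targeted locus were examined because a targeted allele can carry flanking sequence of another strain. Since 0 genes passed the adjusted threshold, the share at an unadjusted p under 0.05 was compared, a choice made after seeing the data. Within 10 Mb on each side of Nkx2-2 it was 4 of 147 genes (2.72%), against 412 of 14494 elsewhere (2.84%), and Fisher's exact test, two-sided, gave p = 1 and an odds ratio of 0.956 (95% interval 0.256 to 2.52).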

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

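An interaction of sex and group was tested only after both sexes were found in each group. It called 3 of the genes tested, named here after their values were seen, with 431 at an unadjusted p under 0.05. With 1 male per group, a difference between sexes cannot be told from a difference of one mouse.

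St3gal4, a sialyltransferase gene, had an interaction of -6.954 on the log2 scale (limma adjusted p = 0.0015). Its values were 359, 272 and 269 FPKM in controls and 3.11, 310 and 290 FPKM in mutants 1 to 3, so the male mutant alone was low. It had 108 reads there, against 9700 to 13959 in the other libraries. The group means of the authors' deposited table, 11517 and 7817, are lower in mutants too. The cause was not tested.

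Mir215, a microRNA gene of 111 bases, had an interaction of -20.2 (limma adjusted p = 0.020). Its values of 148, 0 and 0 FPKM in controls and 0, 144 and 46.0 FPKM in mutants rest on 3, 0, 0, 0, 3 and 1 reads. Snora78, a small nucleolar RNA gene of 157 bases, had an interaction of 6.788 (limma adjusted p = 0.0043). Its values of 0, 6.44 and 5.94 FPKM in controls and 39.7, 23.0 and 22.1 FPKM in mutants rest on at most 1 recovered read each. Both transcripts are shorter than the 210.3 bases taken off each length, so their FPKM and read numbers are unreliable.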

How the results depend on the processing

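Alternatives were chosen before the data were examined, except limma-voom and the use of unadjusted p around Nkx2-2, which were chosen after seeing the data. Tests with edgeR and DESeq2, planned for counts or recoverable reads, were not run: no table gives counts per library, and the recovered reads are estimates from coverage. Leaving out one mouse leaves 2 against 3. For the genes named other than Nkx2-2, 733 values kept direction and side of the threshold under other settings and 1 came to pass. With a mouse left out 393 did so, 14 turned and 1 came to pass. Most of these adjusted p were far from the threshold, close to 1. Depth limits Gast, Nts, Pax4, Mcpt4 and Tff1, which rest on under 40 reads per library on average. The same holds for other genes named, among them Nkx2-2, Lmx1a, Ucn3, Iapp, Pax6, Cpa3, Cpb1, Ctrl, Slc38a11 and Defa21. Except where stated, the cause of a change was not tested. List values are camera adjusted p. With all 6 mice, the direction turned under at least 1 setting for hormones, transcription factors, proliferation, fibroblasts, proximal genes and distal genes.

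With a pseudocount of 1 the hormones stood at 0.852, serotonin members passing numbered 3 and isoforms 3. With a pseudocount of 0.01 acinar markers stood at 0.0529. With no filter the hormones stood at 0.886, and 3 hormones, 2 serotonin members and 1 transcription factor passed over the list alone. With a filter of 1 FPKM, which tests fewer genes, the hormones stood at 0.666, transcription factors 0.854, antimicrobial genes 0.0429, acinar 0.153, stomach 0.0265, distal genes 0.977 and immediate early genes 0.0474. With that filter 2 serotonin members passed, and 1 isoform. With quantile normalization 4 serotonin members passed, and proliferation stood at 0.980, acinar at 0.0866 and proximal genes at 0.940. TMM-type scaling gave acinar 0.0638. Without the trend the hormones stood at 0.925, and 2 serotonin members and 2 transcription factors passed. Array weights gave hormones 0.910, Paneth 0.0595, fibroblasts 0.930 and a log2 change of 0.00915 for Nkx2-2. A sex term gave hormones 0.952, fibroblasts 0.959 and acinar 0.0612. Limma-voom called 11 lists, with goblet, iron and calcium, and immediate early genes at 0.0444, PPAR-alpha genes at 0.0474 and proliferation at 0.956. It passed 3 hormones and 3 serotonin members.

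With an estimated correlation 0 lists passed: serotonin genes stood at 0.837, B cells 0.844, interferon and mast cells 0.902, and Paneth, cholesterol and acinar 0.916. With fry 0 passed: serotonin genes 0.590, B cells 0.60, and Paneth, cholesterol, interferon, mast cells and acinar 0.942. The authors' deposited table has 5 genes. Fisher's exact test for the 20 Mb window around Nkx2-2 gave p = 0.735.

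Replicate numbers were tested as a block, though no label pairs the mice. After group means were removed, controls and mutants of the same number correlated at 0.211, 0.0531 and 0.221, and other pairs at -0.263 to 0.064. Control 2 correlated more with mutant 3 (0.064) than with mutant 2. Replicate 1 was the male in both groups, so the replicate number is partly a term for sex. The correlations neither establish nor exclude a pairing, and none was assumed. The block called 1 gene, Afp (adjusted p = 0.0171), chosen after its values were seen, and 0 isoforms. With the block 850 genes had an unadjusted limma p under 0.05, against 416 in the main fit. The block passed 9 hormones and 5 serotonin members, with PPAR-alpha genes at 0.0217, fibroblasts 0.909, acinar 0.119, stomach 0.0215, clock genes 0.0226 and immediate early genes 0.0430.

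With one mouse left out in turn, called genes ranged from 0 to 3, lists from 6 to 12, isoforms from 0 to 9, hormone members from 3 to 6 and serotonin members from 0 to 4. The genes, chosen after their values were seen, were Snora16a without control 1, Rpl29 without control 2, Hbb-b2, Mir1199 and Mt1 without control 3, Snord15a without mutant 1 and Snora34 without mutant 3. Most are short or share sequence with copies. Log2 changes ranged from -0.233 to 0.0987 for Nkx2-2, -0.0404 to 0.219 for Gip, -0.171 to 0.0110 for Cck, -0.415 to 0.0398 for Fev, -0.539 to 0.127 for Slc38a11, -0.0566 to 0.311 for Neurog3, -0.292 to 0.0286 for Neurod1, -0.0578 to 0.321 for Insm1 and -0.412 to 0.00163 for Lgr5.

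With one mouse left out the direction turned 46 times, in 21 lists: hormones, granule genes, tuft, stem, proliferation, brush border, lipid absorption, MHC class II, antimicrobial, T cell, fibroblasts, smooth muscle, endothelium, neurons and glia, islets, proximal, distal, clock, immediate early, blood and sex genes. The 7 lists that passed the threshold kept their direction. List values with one mouse left out ranged as follows: hormones 0.295 to 0.943, granule genes 0.0302 to 0.823, goblet 0.0377 to 0.397, Paneth 6.60e-08 to 0.367, tuft 0.120 to 0.829, stem 0.0155 to 0.996, proliferation 0.226 to 0.930, brush border 4.45e-06 to 0.915, lipid absorption 0.0187 to 0.638, iron and calcium 0.00363 to 0.782, PPAR-alpha 7.99e-05 to 0.930, cholesterol 3.84e-14 to 0.504, interferon 8.79e-06 to 0.807, MHC class II 3.73e-08 to 0.944, antimicrobial 6.86e-06 to 0.893, T cell 0.0312 to 0.650, and mast cell 8.56e-07 to 0.0945. Fibroblasts ranged from 0.0106 to 0.981, smooth muscle 0.0400 to 0.943, endothelium 0.0120 to 0.832, neurons and glia 0.0155 to 0.847, acinar 2.91e-07 to 0.526, islets 0.0555 to 0.872, stomach 0.00457 to 0.738, proximal 0.504 to 0.947, distal 0.101 to 0.916, clock 0.143 to 0.943, immediate early 0.00114 to 0.851, blood 0.401 to 0.912 and sex genes 0.242 to 0.909.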

Other observations

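Further values concern defence and detoxification genes, of which Reg3b and Hmox1 belong to the fixed lists. Reg3b, an antimicrobial lectin gene, was at 40406, 33825 and 23954 FPKM in controls and 8291, 30004 and 4115 FPKM in mutants. Hmox1, a heme-degrading enzyme gene, was at 4.50 ± 0.399 FPKM in controls and 18.9, 5.77 and 6.49 FPKM in mutants. The following genes were chosen after their values were seen. Mt2, a metallothionein gene, was at 112 ± 58.7 and 253 ± 92.3 FPKM. The glutathione transferase genes Gsta1 and Gstm3 were at 557 ± 228 and 942 ± 291 FPKM and at 265 ± 82.1 and 466 ± 121 FPKM. They share sequence with close copies and are uncertain. Cbr3, a carbonyl reductase gene, was at 8.14 ± 2.90 and 30.2 ± 19.8 FPKM, with 52.15, 13.81 and 24.49 FPKM in mutants 1 to 3. None of these passed over all genes.

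Of the tests below, those of the share of endocrine cells, of the mix of sexes and of Gast alone were chosen only after their results were seen, as was the use of unadjusted p near Nkx2-2.

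The serotonin genes were lower as a list. If the mutants had fewer endocrine cells of every kind, with levels per cell unchanged, no other hormone should be higher. Yet 3 were, over the hormone list alone. Of these Ghrl and Sst passed in every setting, while Gast did not. Levels in whole tissue do not separate cell number from expression per cell, so fewer endocrine cells cannot be excluded. Scaling did not remove the difference, as the highest list median under quantile and TMM-type scaling was -0.484. The groups held the same number of males, a difference of 0. The cause stays open, and the call is lost with an estimated correlation (0.837). Every mutant also carries Villin-Cre and lacks the floxed copy in epithelium, unlike any control. The difference thus cannot be assigned to the SD form.

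Ghrl and Gast were higher, and both are abundant in stomach. If stomach tissue at the edge of the sample caused this, its abundant genes should rise with them. The summed FPKM of Atp4a, Atp4b, Gkn1, Gkn2, Gif and Pgc was 3.61 ± 4.07 in controls and 4.29 ± 3.56 in mutants, a rise of 0.684, against a rise of 142 for Ghrl, so stomach tissue does not account for Ghrl by this measure. Gast rose by only 1.43 FPKM. Tff1 and Ctse, stomach genes outside the sum, were higher too, though each passed in only part of the settings. Gif, a stomach gene within the sum, went the other way, with 34 reads in controls and 0 in mutants. For Gast this stays open.

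Detoxification genes led to a list of 20 NRF2 targets not looked at before their test. Of these 16 had log2 changes above 0, with a median log2 change of 0.14 (camera p = 1.84e-05; p = 0.0706 with an estimated correlation), and 0 passed over the list alone. Gstm1 was at 139 ± 32.8 and 248 ± 75.0 FPKM, and Blvrb at 55.4 ± 3.86 and 69.6 ± 6.37 FPKM. Log2 changes were near 0 for Gclc (0.07), Txnrd1 (-0.04), Srxn1 (0.02) and Slc7a11 (-0.07), against 0.30 for Nqo1. Gstm1, Gstm2, Gsta4 and Cbr1 lie close to Gstm3, Gsta1 and Cbr3, which prompted the list. They are therefore not independent of those genes, and Gstm1 carries the same caveat on close copies as Gstm3. The other members come from the same mice as the genes that prompted the list. Members that vary together (estimated correlation 0.14) can follow those genes whatever the group, so this is not an independent test. A wider NRF2 response stays possible, resting on the preset correlation.

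Within 20 Mb of Nkx2-2, 10 of 325 genes had an unadjusted p under 0.05, and Fisher's exact test gave p = 0.735 (odds ratio 1.09, 95% interval 0.513 to 2.05). Ptpra, 16.68 Mb away and chosen after its values were seen, was at 8.13 ± 1.14 and 13.3 ± 0.077 FPKM. The interval cannot tell whether flanking sequence matters.

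The 6 libraries can be split 3 against 3 in 10 ways, which cannot give a share under 0.05. The real split called 0 genes and the highest other 9; any split reaches a count of 0, so its 10 of 10 tests nothing. It called 5 isoforms against 9 in the highest other, and 6 of the 10 splits, the real one included, called at least as many. It passed 7 lists, and every other split passed at least as many, up to 22. For the serotonin list the real p was 1.13e-06 and the smallest other 0.00144, so only the real split reached it.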
